A study of Homo sapiens with 12 samples.

How the data were processed

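RNA was sequenced from HEK293T cells, a human embryonic kidney line that carries the SV40 large T antigen, and from 2 knockout lines made from it, labelled KO1 and KO9 and called clones here. Each line gave input RNA, the total RNA, and polysome RNA, the RNA bound by several ribosomes at once. Each line and fraction had 2 libraries, so that 12 libraries fell into 6 groups. The labels do not name the gene that was removed. Only the name of the deposited table pairs the knockout with UBAP2L, and UBAP2L was therefore read in every library before anything else. Per the labels' protocols, RNA was extracted with Trizol and libraries were made with a stranded mRNA kit, a kind that selects poly(A) RNA. The labels do not say whether the 2 replicates of a group came from separate cultures. P-values here measure only the spread between samples labelled as replicates.

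The authors deposited a single table of RPKM (reads per kilobase of gene and per 1e6 reads) for 11623 genes and all 12 libraries. Per the submitters' processing notes, cutadapt 1.4.0, STAR 2.4.0i, featureCounts 1.5.0 and DESeq2 1.10.1 were used with the genome build hg19, and the notes give neither order nor role. The lowest mean RPKM of a gene in the deposited table was 0.961, so that genes of low level had been left out before deposition by a rule that is not stated. For each library 1 whole number was sought that turns RPKM times gene length into whole read numbers. It did so within 0.01 for the 1522 genes whose versioned identifier is in GENCODE release 29. The length of each of the 11623 genes was then taken as the smallest that gave whole reads in every library. Of the 1522 genes, 1521 gave back that release's merged exon length. The whole number is the read total by which the authors divided. Gene symbols came from the tables supplied with the annotation, for 11161 genes. Type and GC content came from GENCODE 29 on GRCh38, matched by identifier without version, for 11395 genes (98.0%). No coordinate of the authors' build was used.

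Genes with an RPKM of at least 1 in at least 2 libraries were tested, which kept all 11623. Each library was divided by a median-of-ratios factor computed from the RPKM values, and log2(value + 1) was analysed. The added 1 makes the fold changes of genes of low RPKM smaller than their ratios. limma 3.58.1 in R 4.3.3 fitted 6 group means in 1 model, with a moderated test whose prior followed the mean level. All tests were two-sided. P-values were adjusted by Benjamini and Hochberg over all genes of a comparison, and an adjusted p under 0.05 was called. The 12 comparisons were polysome against input over the 3 lines, the clones together and each clone against parental cells (in input, on polysomes, and as the change of polysome over input), and KO9 against KO1 (in input and as polysome over input). Polysome over input is the difference of the differences, so it needs 8 or 12 libraries and has the largest error. With 2 libraries per group the fit shares 1 spread per gene over all groups, and a library left alone in its group is assumed to vary like the others.

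The groups, tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined. The rule names UBAP2L, the 8 genes with the largest increase and the 8 with the largest decrease per main comparison among those past the threshold with a mean RPKM of at least 5. For the clones it also asks for the same direction in both, and in input and on polysomes for all 4 clone libraries beyond both parental ones. Where fewer than 5 passed, the 5 genes with the smallest p in that direction are given as not past the threshold. It adds up to 4 members, those with the smallest p, of each called list, and skips genes without a symbol. Not every gene that the rule names is reported here. After the data were seen, the same rule was also applied to polysome over input without input KO1 replicate 2. Of 28 gene lists, 24 had at least 5 measured members and were tested in the 4 main comparisons with limma's camera at a preset correlation between genes of 0.01, adjusted over the 24 lists. They cover cytosolic and mitochondrial ribosomal proteins, other mRNAs with a terminal oligopyrimidine (TOP) start, noncoding hosts of small nucleolar RNAs, translation initiation factors, aminoacyl-tRNA synthetases, stress granule and UBAP2L-associated proteins, mRNA decay factors, integrated stress response targets, heat shock proteins, endoplasmic reticulum chaperones, proteasome subunits, p53 targets, DNA replication, mitosis, replication-dependent histones, immediate early genes, interferon-stimulated genes, cholesterol synthesis, glycolysis and hypoxia, nuclear-encoded respiratory chain subunits, mitochondrially encoded mRNAs, neuronal genes that HEK293 cells express, and nuclear or untranslated long RNAs. The 4 lists of other cell types had too few members in the table: 4 of 20 fibroblast, 2 of 18 epithelial, 0 of 17 haematopoietic and 0 of 16 hepatocyte markers.

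Alternatives were pseudocounts of 0.1 and 5, a minimum RPKM of 5, the deposited RPKM without scaling, quantile normalization, the replicate number as a block, a robust prior, array weights, a fit on the libraries of a comparison alone, leaving out each library in turn, a loess correction for length and GC content with span 0.5, and for the lists an estimated correlation and fry. After the data were seen, limma voom on the recovered reads, fits without input KO1 replicate 2 that combine it with voom or the loess correction, a fit on 10015 protein-coding genes, list medians under each scaling, list member counts and genes called in both clones with each library left out, the clones against different parental libraries, list tests with an estimated correlation and each library left out, and list tests between the clones were added. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9, and data.table (version 1.17.8) in R, handled tables and figures.

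The method was tested on simulated data with the observed spread and 200 changed genes. Noise was drawn separately for each gene, so shifts shared by many genes, as in input KO1 replicate 2, were not simulated. The shares and false calls given here hold only for such noise. Of genes changed 2-fold, 92.5% were recovered for polysome against input, 68.7% for the clones in input, 53.7% on polysomes and 26.9% for polysome over input. Without input KO1 replicate 2 these shares were 100, 98.5, 100 and 88.1%. At most 1 unchanged gene was called with all libraries, and at most 9 without that library.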

Results

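The data were 12 RNA libraries of HEK293T cells and of the knockout clones KO1 and KO9, with input and polysome RNA of each line and 2 libraries per group. The title of the series places them in a study of factors that regulate mRNA stability and translation, and polysome RNA next to input RNA asks how much of each mRNA is engaged by ribosomes. The read totals behind the deposited RPKM were, in units of 1e6 reads, 63.9 and 69.3 for the parental input libraries, 33.6 and 17.8 for input KO1, and 36.5 and 28.1 for input KO9. On polysomes they were 33.7 and 20.2 for parental cells, 25.2 and 21.5 for KO1, and 7.43 and 14.4 for KO9. The median gene had 246 recovered reads in the shallowest library (polysome KO9 replicate 1) and 1914 in the deepest. Transcripts of the mitochondrial genome took 8.77 and 8.12% of the parental input table, 5.49 and 4.11% of input KO1, 7.61 and 7.51% of input KO9, and 1.18 to 2.14% of the polysome libraries.

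UBAP2L (ENSG00000143569.14, chromosome 1, 154220179 to 154271510 on the plus strand of GRCh38) encodes an RNA-binding protein of stress granules, which are assemblies of untranslated mRNA and protein. In input its RPKM was 15.2 ± 0.4004 (SD, n = 2) in parental cells, 8.88 ± 0.120 in KO1 and 7.32 ± 0.239 in KO9. On polysomes it was 14.3 ± 1.47 in parental cells, 8.15 ± 0.393 in KO1 and 5.53 ± 1.21 in KO9. All 8 clone libraries lay below all 4 parental ones. In limma's test UBAP2L fell in the clones together by 1.07 on the log2 scale in input (SE 0.12, adjusted p = 0.00176) and by 0.94 on polysomes (adjusted p = 0.00306), which left 0.475 and 0.520 of the parental level. Each clone passed alone, with log2 fold changes in input of −0.99 for KO1 and −1.16 for KO9. The mRNA was lower, not lost, and a sequence change in it cannot be seen in gene totals. Without parental input replicate 2 the input adjusted p was 0.0503, and without parental polysome replicate 1 the polysome adjusted p was 0.0852. Over all alternatives the input value ranged from 1.90e-06 to 0.0553 and the polysome value from 3.88e-06 to 0.0852. UBAP2L did not pass the test for polysome over input (log2 0.13, SE 0.17, adjusted p = 0.99995), and the sign of that value was negative (−0.15) without scaling.

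**Figure D1:**
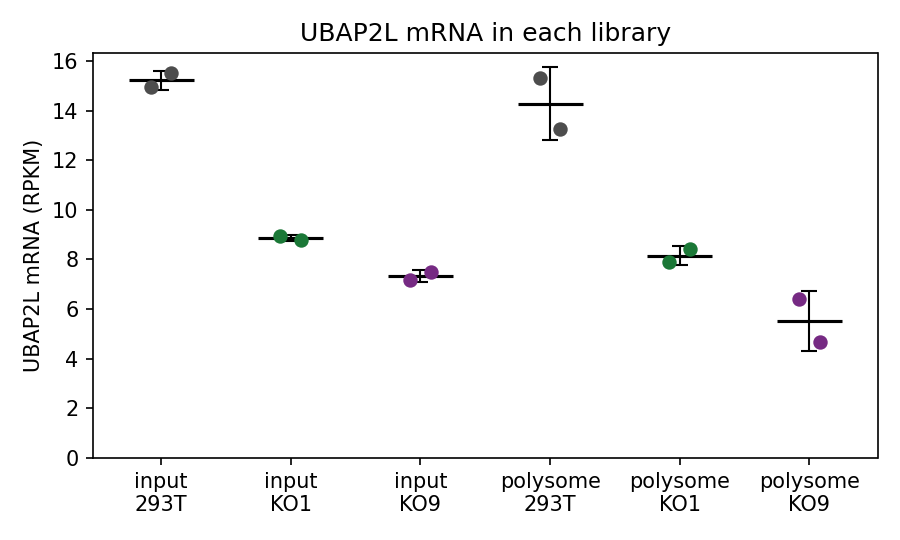
UBAP2L mRNA (RPKM, vertical axis) in each of the 12 libraries, as points, with the mean and SD of the 2 libraries per group, for input and polysome RNA of the 3 lines. Parental values were 13.2 to 15.5 and clone values 4.67 to 8.96.

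The 2 libraries of a group differed by an SD across genes of 0.119 to 0.220 (log2) in 5 of the 6 groups, and by 0.650 in input KO1, where 1360 genes differed by more than 1. Input KO1 replicate 2 stood apart: on the second principal component, which held 25.4% of the variance, it lay at 56.6 and the other libraries at −14.3 to 9.55. The first component (43.5%) separated input from polysome RNA in the other 11 libraries. Against replicate 1, replicate 2 had lower heat shock (median log2 −0.80), other TOP (−0.77), mitosis (−0.70), aminoacyl-tRNA synthetase (−0.67), cytosolic ribosomal protein (−0.67) and stress granule mRNAs (−0.64), and higher noncoding hosts of small nucleolar RNAs (0.52). Across genes, which are not independent replicates, this difference went with GC content (Spearman 0.45) and gene length (−0.22). Because all 6 groups share 1 spread per gene, this library widens the error of every comparison, and counts without it are given too. Leaving out replicate 1 of that group instead also removes the wide pair from the spread but keeps the divergent library as the value of the group.

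**Figure D2:**
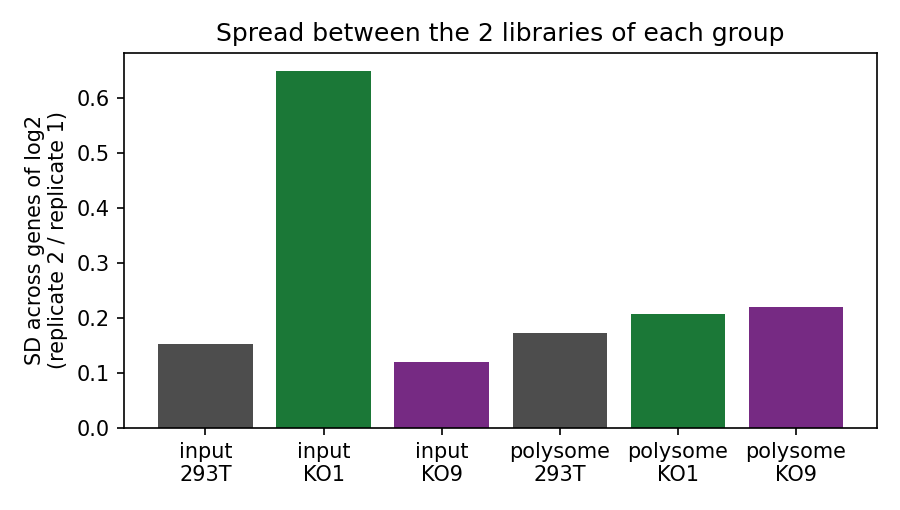
SD across 11623 genes of the log2 ratio of replicate 2 to replicate 1 (vertical axis) in each of the 6 groups, as bars. Input KO1 reached 0.650, and the next highest group, polysome KO9, 0.220.

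Polysome RNA was compared with input RNA to show which RNAs were engaged by ribosomes. RNAs of the mitochondrial genome, which are translated by ribosomes inside mitochondria, were the most depleted: 11 of 13 mitochondrial mRNAs fell, with a median log2 fold change of −2.67, and none rose (adjusted p = 0.621 for the list with an estimated correlation). The mitochondrial ribosomal RNA MT-RNR1 went from an RPKM of 2476 ± 53.1 in parental input to 77.8 ± 3.50 on parental polysomes (n = 2 each; log2 −4.25 over the 3 lines, SE 0.22, adjusted p = 1.84e-06), and MT-CO2, a subunit of cytochrome c oxidase, fell by 3.396 (SE 0.18, adjusted p = 1.82e-06). IRS4, an insulin receptor substrate, fell by 3.34, from 50.5 ± 2.001 to 6.06 ± 0.724 RPKM in parental cells (adjusted p = 1.31e-06). Nuclear-encoded subunits of the respiratory chain went the other way, with 45 of 72 higher, 2 lower and a median of 0.44 (ATP5F1D 1.04, NDUFC2 1.003; adjusted p = 0.766 with an estimated correlation). Mitochondrial ribosomal proteins had 24 of 66 higher and 1 lower (MRPS6 0.9993, SE 0.10), with adjusted p = 0.845 with an estimated correlation.

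Among single genes the largest increases were in CCDC85B (1.54, SE 0.33, adjusted p = 0.00358), the AP-1 member JUND (1.37, SE 0.19, adjusted p = 0.000301) and the proprotein convertase inhibitor PCSK1N (1.37, SE 0.29), with C4orf48 at 1.48. Of 10 immediate early genes, which respond first to growth signals, 6 rose on polysomes and none fell (IER2 0.98), and of 7 replication-dependent histones, 5 rose (H2AX 1.22). These lists had adjusted p = 0.845 and 0.621 with an estimated correlation. The library kit was of a kind that selects poly(A) RNA. Histone values here and in the later comparisons therefore cover histone mRNAs with a poly(A) tail and may miss others. Of 28 genes of mitosis 14 fell, among them the kinases TTK (−1.05), NEK2 (−0.75) and CDK1 (−0.65), while 3 rose, UBE2C among them (0.74). Nuclear or untranslated long RNAs fell in 6 of 10 and rose in 1 (DLEU2 −0.99, OIP5-AS1 −0.92, NEAT1 −0.50). The mitosis list had adjusted p = 0.963 and the long RNAs 0.621 with an estimated correlation. Several other large changes belonged to near-identical copies (NPIPA5, NPIPA7 and the pseudogenes MTCO2P12 and MTCO2P2), whose reads cannot be told apart with confidence.

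In limma's test 5796 genes passed for polysome against input, 2899 higher and 2897 lower, and 8305 without input KO1 replicate 2, with all 5796 among them in the same direction. Without scaling 66.3% of the called genes were higher on polysomes rather than 50.02%, and the median of all genes moved from 0.01 to 0.12. The camera test called the mitochondrial mRNAs (adjusted p = 5.01e-08), the respiratory chain (1.07e-06), mitochondrial ribosomal proteins (0.00146), and immediate early genes, histones, mitosis and long RNAs (0.0350 each), with the same signs of the medians under every scaling. None of the 7 held with an estimated correlation, with all libraries or with any 1 left out, where adjusted p reached 0.989; the lowest of any alternative was 2.11e-10. Adjusted over the list alone, the counts (higher and lower) were 0 and 11 for mitochondrial mRNAs, 46 and 2 for the respiratory chain, 23 and 1 for mitochondrial ribosomal proteins, 6 and 0 for immediate early genes, 6 and 0 for histones, 3 and 14 for mitosis, and 1 and 7 for long RNAs. Of 40 named genes past the threshold, 39 stayed past it whichever library was left out. The exception was the histone H2BC5 (0.24, adjusted p = 0.0188), lost without parental input replicate 1, input KO9 replicate 2 or parental polysome replicate 2. Without input KO1 replicate 1 the immediate early (0.0777), mitosis (0.0777) and long RNA lists (0.0603) were no longer called, and the last was also lost without replicate 2. Higher mitochondrial ribosomal proteins numbered 37 and 44 without input KO1 replicate 1 and 2, with 3 and 8 lower, and 15 without parental input replicate 1 or polysome KO9 replicate 2. Lower respiratory chain subunits numbered 6 without either input KO1 library, higher genes of mitosis 5 without replicate 2, and higher histones 3 without parental input replicate 1, input KO9 replicate 2 or parental polysome replicate 2.

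The clones were compared with parental cells in input RNA, which shows the level of each mRNA. Cytosolic ribosomal protein mRNAs were lower as a group: 34 of 78 fell, none rose, and the median log2 fold change was −0.79 (adjusted p = 0.302 for the list with an estimated correlation). The count was 62 without input KO1 replicate 2 and 0 without either parental input library. The medians were −1.08 in KO1 and −0.52 in KO9. RPS14 went from 449 ± 3.15 RPKM in parental cells to 224 ± 60.8 in KO1 and 290 ± 20.4 in KO9 (n = 2 each; log2 −1.08, SE 0.19, adjusted p = 0.0106), and RPL10 fell by 0.95. Other mRNAs with a TOP start, the sequence by which growth signals control the synthesis of the translation machinery, also fell: 7 of 18, none higher, median −0.78 (adjusted p = 0.302 with an estimated correlation). The elongation factor EEF2 went from 756 ± 8.15 to 400 ± 34.997 and 385 ± 4.41 RPKM (log2 −1.20, SE 0.17, adjusted p = 0.00504), and EIF4B (−1.42), RACK1 (−0.94) and EIF3H (−1.07) fell with it.

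Targets of p53 were higher: 6 of 18 rose, none fell, and all 18 had a positive value, with a median of 0.39 (adjusted p = 0.302 with an estimated correlation). The count was 12 without input KO1 replicate 2, and 3 and 0 without parental input replicate 1 and 2. CDKN1A, the cyclin-dependent kinase inhibitor p21, rose from 11.9 ± 3.601 to 54.5 ± 14.0 RPKM in KO1 and 36.3 ± 0.216 in KO9 (log2 1.60, SE 0.23, adjusted p = 0.00504). MDM2, which degrades p53, rose by 0.79, as did the exonuclease AEN, and ZMAT3 rose by 0.77. HEK293T cells carry the large T antigen, which binds p53. Respiratory chain subunits fell in 9 of 72 (NDUFA5 −0.86, ATP5MF −0.76), and mitochondrial mRNAs in 4 of 13 (MT-CO1 from 16492 ± 206 to 8470 ± 32.8 and 11267 ± 970 RPKM, log2 −1.01). These 2 lists had adjusted p = 0.546 and 0.647 with an estimated correlation. Their medians were −0.45 and −1.09 in KO1 (−0.30 for the first without input KO1 replicate 2) and −0.20 and −0.25 in KO9 (−0.12 for the second without input KO9 replicate 2). The respiratory chain was not called between the clones (adjusted p = 0.0660, and 0.2001 without input KO1 replicate 2), except without input KO9 replicate 2 (0.0124, or 0.985 with an estimated correlation). Integrated stress response targets, the genes switched on by ATF4, had 7 of 26 lower and 1 higher, among them SHMT2 (−0.78) and CTH (−0.79), enzymes of serine and cysteine metabolism, and DDIT4 (−0.63), and adjusted p = 0.562 with an estimated correlation. The median was −0.53 in KO9 (2 of 26 positive) and 0.15 in KO1 (15 of 26). The KO1 value rested on single libraries, with 0.30 and 0.02 without input KO1 replicate 1 and 2 and 0.31 and 0.08 without parental input replicate 1 and 2. The interferon-stimulated genes IFITM1 (−0.98) and IFITM3 (−0.73; −0.13 in KO1 and −1.34 in KO9) fell, 2 of 7 (adjusted p = 0.302 with an estimated correlation). Of 10 immediate early genes, CCN1 (0.56) and IER2 (0.69) rose and MYC fell by 1.22, from 27.7 ± 2.24 to 13.2 ± 1.24 and 13.9 ± 0.277 RPKM (SE 0.13, adjusted p = 0.00141). The histones H2AX (0.98), H2BC5 (0.57) and H2BC21 (0.46) rose, 3 of 7, and of 20 aminoacyl-tRNA synthetases QARS1 passed (−0.68), or 8 lower and 1 higher without input KO1 replicate 2. With an estimated correlation the immediate early genes had adjusted p = 0.641, the histones 0.302 and the synthetases 0.546.

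Among single genes, CRABP2, a retinoic acid carrier, fell by 2.42 (SE 0.16, adjusted p = 5.47e-05), from 22.8 ± 0.820 to 6.001 ± 1.17 and 2.95 ± 0.224 RPKM. VAMP8, a protein of vesicle fusion, fell by 2.31 (SE 0.14, adjusted p = 2.48e-05), and the long noncoding RNA LINC01605 by 2.07. The largest mean increase, that of the Wnt receptor FZD10 (2.99, SE 0.10, adjusted p = 3.62e-07), came almost wholly from KO1: 0.397 ± 0.0483 RPKM in parental cells, 66.8 ± 5.31 in KO1 and 1.06 ± 0.0722 in KO9. HSPA1A and HSPA1B, near-identical genes of the inducible heat shock protein HSP70, rose by 1.56 and 1.52, and BASP1 rose by 1.28, with 2.28 in KO1 and 0.27 in KO9. NGRN rose by 1.78, and its replicates in KO1 differed widely (28.0 ± 20.7 RPKM).

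In limma's test 1277 genes passed in input, 615 higher and 662 lower. This count moved with the library left out, also with polysome libraries, which this comparison does not use. Leaving out a library changes the error and the shared spread, so the count does not show which library the changes rest on. The ribosomal protein median, −0.79 with all libraries, was −0.80 and −0.77 without parental input replicate 1 and 2. It was −0.96 and −0.61 without input KO1 replicate 1 and 2, and −0.82 and −0.77 without input KO9 replicate 1 and 2. All 1277 were among the 4192 (2145 higher, 2047 lower) found without input KO1 replicate 2. Without scaling 89.8% of called genes were higher, against 48.2% with it, and the median of all genes was 0.22. Changes are therefore relative to the median gene. Of 48 named genes past the threshold, 7 stayed past it whichever library was left out: FZD10, CRABP2, VAMP8, LINC01605, MYC and the mitochondrial pseudogenes MTCO1P53 and MTCO1P40. The number still past was 10 and 7 without parental input replicate 1 and 2, 48 without either input KO1 library, 20 and 18 without input KO9 replicate 1 and 2, 38 without either parental polysome library, 43 without either polysome KO1 library and 40 without either polysome KO9 library.

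The camera test called 10 lists in input: ribosomal proteins (adjusted p = 8.17e-21), other TOP mRNAs (3.62e-07), respiratory chain (6.90e-07), p53 targets (9.93e-06), aminoacyl-tRNA synthetases (0.00574), mitochondrial mRNAs (0.0434), and histones, stress response targets, immediate early and interferon-stimulated genes (0.0487 each). None held with an estimated correlation, with all libraries or with any 1 left out, where adjusted p reached 0.902; the lowest of any alternative, for ribosomal proteins, was 9.35e-31. Adjusted over the list alone, the counts (higher and lower) were 0 and 55 ribosomal proteins, 1 and 14 other TOP mRNAs, 0 and 15 respiratory chain subunits, 7 and 0 p53 targets, 0 and 1 synthetases, 0 and 4 mitochondrial mRNAs, 3 and 0 histones, 1 and 10 stress response targets, 5 and 1 immediate early and 0 and 3 interferon-stimulated genes. The ribosomal protein median was −0.54 without scaling and −0.32 with quantile normalization, the median of mitochondrial mRNAs turned to 0.09 with quantile normalization, and that of stress response targets turned to 0.09 without scaling. The first 5 lists were called whichever library was left out. Mitochondrial mRNAs were lost without parental input replicate 1, input KO1 replicate 1 or 2 or input KO9 replicate 2 (adjusted p up to 0.121). Histones (up to 0.0997) were lost without parental input replicate 1, input KO1 replicate 1 or polysome KO9 replicate 1 or 2, and interferon-stimulated genes (up to 0.193) without any of these or input KO9 replicate 2. Stress response targets (up to 0.216) were lost without any of these last 5 or polysome KO1 replicate 1 or 2. Immediate early genes (up to 0.0932) were lost without parental input replicate 1 or 2, input KO1 replicate 2, input KO9 replicate 2 or polysome KO9 replicate 1 or 2.

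The member counts of these lists in input moved with single libraries. Leaving out input KO1 replicate 1 and 2 gave 63 and 62 lower ribosomal proteins, 15 and 16 other TOP mRNAs, 40 and 26 respiratory chain subunits, 14 and 8 synthetases, 10 and 13 stress response targets, 6 and 4 mitochondrial mRNAs and 3 and 4 interferon-stimulated genes. In the same fits 12 and 12 p53 targets, 5 and 3 histones and 7 and 4 immediate early genes were higher, and without replicate 1 also 8 respiratory chain subunits and 8 stress response targets. Without either parental input library no member of the 10 lists passed except MYC and, without replicate 1, 3 p53 targets. Without input KO9 replicate 1 and 2 there were 3 and 1 ribosomal proteins, 3 and 2 other TOP mRNAs, 1 and 0 respiratory chain subunits, 2 and 2 p53 targets, 2 and 2 stress response targets, 1 and 1 interferon-stimulated genes and 0 and 1 histones, with no synthetase or mitochondrial mRNA and no immediate early gene but MYC. Without either parental polysome library 17 ribosomal proteins, 3 respiratory chain subunits and 1 mitochondrial mRNA were lower, and without either polysome KO9 library 22 ribosomal proteins and 1 mitochondrial mRNA.

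In each clone taken alone, KO1 and KO9 had 57 and 3 ribosomal proteins, 12 and 3 other TOP mRNAs, 20 and 1 respiratory chain subunits and 5 and 0 mitochondrial mRNAs past the threshold as lower in input. Without input KO1 replicate 2 these were 62 and 51, 15 and 12, 21 and 17, and 5 and 3, and without replicate 1 they were 62 and 52, 15 and 12, 42 and 17, and 9 and 3. Without parental input replicate 1 KO1 had 0, 1, 2 and 0 in that order, without replicate 2 it had 1, 1, 0 and 0, and KO9 had none in either fit. Respiratory chain subunits in KO1 numbered 7 without either input KO9 library, 9 without either parental polysome library and 10 without either polysome KO1 library. No ribosomal protein or respiratory chain subunit passed in KO9 without any 1 of the libraries other than input KO1, and no other TOP mRNA without either input KO9 library. The medians of the other lists in KO1 and KO9 were −1.06 and −0.56 for other TOP mRNAs, 0.46 and 0.48 for p53 targets, 0.48 and 0.29 for histones, −0.37 and −0.23 for synthetases, 0.61 and 0.08 for immediate early genes and −0.08 and −0.13 for interferon-stimulated genes. The KO1 medians without input KO1 replicate 1 and 2 were −0.65 and −0.09 for synthetases and −0.14 and −0.23 for interferon-stimulated genes. In KO9 the median of interferon-stimulated genes was −0.23 without parental input replicate 2 and −0.08 without input KO9 replicate 1, and that of immediate early genes 0.03 without parental input replicate 2 and 0.15 without input KO9 replicate 2.

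The same comparison on polysomes shows the mRNAs that ribosomes held. Ribosomal protein mRNAs were not lower there: 65 of 78 had a positive value, with a median of 0.24 (adjusted p = 0.565 for the list with an estimated correlation). KO9 had a median of 0.42 with 76 of 78 positive, and KO1 0.01 with 43 of 78, or −0.07 and 0.16 without polysome KO1 replicate 1 and 2, and 0.05 and 0.003 without parental polysome replicate 1 and 2. RPS19 (0.74, SE 0.18, adjusted p = 0.0450) and RPL7A (0.58), which lies near 3 RPKM and has many copies, passed as higher, or 22 higher and 1 lower without input KO1 replicate 2. Targets of p53 were higher again, with 3 of 18 past the threshold (CDKN1A 1.53, PHLDA3 1.13, AEN 0.73) and a median of 0.31 (adjusted p = 0.545 with an estimated correlation). Of 7 histones, H2BC5 went from 4.06 ± 0.332 to 9.32 ± 0.230 and 8.92 ± 0.518 RPKM (log2 1.03, SE 0.11, adjusted p = 0.00118) and H2BC21 rose by 0.60 (adjusted p = 0.139 for the list with an estimated correlation). The proteasome, which degrades tagged proteins, had 2 of 29 subunits higher (PSMC4 0.76, PSMC5 0.54) and a median of 0.22 (adjusted p = 0.552 with an estimated correlation). Heat shock genes had 4 of 19 higher, HSPA1A (1.59), HSPA1B (1.62), BAG3 (0.80) and DNAJB1 (0.77), with adjusted p = 0.552 with an estimated correlation. Stress response targets had 4 of 26 lower (CTH −0.82, PCK2 −0.70, DDIT4 −0.62, SHMT2 −0.60) and 1 higher, with a median of 0.12 in KO1 (15 of 26 positive; −0.01 without parental polysome replicate 2) and −0.48 in KO9 (2 of 26). The clones were not tested against each other on polysomes. Aminoacyl-tRNA synthetases had 3 of 20 lower (QARS1 −0.60, GARS1 −0.56, YARS1 −0.46). Both lists had adjusted p = 0.552 with an estimated correlation. Of 22 genes of cholesterol synthesis none passed, or 8 higher and 2 lower without input KO1 replicate 2 (adjusted p = 0.545 for the list with an estimated correlation). The higher values were those of KO1 (median 0.35, 19 of 22 positive), with 0.07 and 14 of 22 in KO9. The medians in KO1 and KO9 were 0.15 and 0.33 for p53 targets, 0.51 and 0.61 for histones, 0.23 and 0.24 for the proteasome, 0.22 and 0.13 for heat shock genes and −0.08 and −0.27 for synthetases. Without polysome KO1 replicate 1 and 2 the KO1 median of synthetases was −0.05 and −0.15, that of heat shock genes was 0.13 without replicate 2, and that of p53 targets 0.24 without replicate 1 and 0.28 without parental polysome replicate 1. In KO9 heat shock genes had 0.03 and 0.19 without parental polysome replicate 1 and 2 and 0.20 and 0.08 without polysome KO9 replicate 1 and 2, p53 targets 0.20 without parental polysome replicate 2, and the proteasome 0.14 without polysome KO9 replicate 2. For both clones together p53 targets had 0.19 without parental polysome replicate 2.

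The single genes were largely those of input. VAMP8 fell by 2.20 (SE 0.14, adjusted p = 3.29e-05), from 23.3 ± 0.805 to 8.31 ± 1.92 and 1.86 ± 0.255 RPKM, CRABP2 by 2.13, LINC01605 by 1.62 and MYC by 1.24. FZD10 rose by 3.29 (6.04 in KO1 and 0.53 in KO9). HEXIM1, an inhibitor of the elongation kinase P-TEFb, rose by 1.16 (SE 0.13, adjusted p = 0.00181), C12orf57 by 1.27 in either clone, BEX5 by 1.51, and TMSB4X, an actin-binding peptide, by 1.65 (2.50 in KO1 and 0.80 in KO9). CYBA, a subunit of the NADPH oxidase, fell by 1.36 and EIF4B by 1.16.

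In limma's test 664 genes passed on polysomes, 255 higher and 409 lower. The count was 278 and 280 without parental input replicate 1 and 2, 3892 and 3882 without input KO1 replicate 1 and 2, 259 and 260 without input KO9, 35 and 42 without parental polysome, 285 and 164 without polysome KO1, and 281 and 250 without polysome KO9 replicate 1 and 2. All 664 were among the 3882 (1902 higher, 1980 lower). Without scaling 27.6% of called genes were higher rather than 38.4%. Of 33 named genes past the threshold, FZD10, VAMP8, CRABP2, LINC01605, MYC and H2BC5, 6 in number, stayed past it whichever library was left out. The number still past was 33 without either input KO1 library, 23 without any other input library, 8 without either parental polysome library, 22 and 16 without polysome KO1 replicate 1 and 2, and 18 and 22 without polysome KO9 replicate 1 and 2.

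The camera test called 8 lists on polysomes: ribosomal proteins and p53 targets (adjusted p = 0.000265 each), histones (0.000389), proteasome (0.00126), cholesterol synthesis, stress response targets and synthetases (0.0308 each) and heat shock genes (0.0433), with the same signs of the medians under every scaling. With an estimated correlation none was called, with all libraries or with any 1 left out, where adjusted p reached 0.718; the lowest of any alternative was 3.88e-06. Adjusted over the list alone, the counts (higher and lower) were 1 and 0 ribosomal proteins, 7 and 0 p53 targets, 5 and 0 histones, 2 and 0 proteasome subunits, 3 and 1 genes of cholesterol synthesis, 2 and 10 stress response targets, 1 and 4 synthetases and 6 and 0 heat shock genes. The first 5 were called whichever library was left out. Stress response targets were lost without parental polysome replicate 1 or polysome KO9 replicate 1 (adjusted p up to 0.250), synthetases also without polysome KO1 replicate 1 (up to 0.127), and heat shock genes without these 2 or polysome KO1 replicate 2 (up to 0.164). Without either input KO1 library 22 ribosomal proteins, 10 p53 targets, 5 histones, 12 proteasome subunits, 8 genes of cholesterol synthesis and 7 heat shock genes were higher, and 12 stress response targets, 7 synthetases and 4 heat shock genes lower. Without parental polysome replicate 1 and 2 there were 1 and 0 p53 targets, 0 and 1 lower stress response targets and 1 and 1 histones, and no ribosomal protein, proteasome subunit, synthetase or heat shock gene. Without any 1 of the other 8 libraries there was 1 ribosomal protein, 1 proteasome subunit, no synthetase, and 1 lower stress response target (2 without polysome KO9 replicate 2). Heat shock genes also fell to 0 without polysome KO1 replicate 2 or polysome KO9 replicate 1, and p53 targets to 1 without polysome KO1 replicate 2 or polysome KO9 replicate 2.

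The change of polysome over input sets the change on polysomes against the change in level. A higher value can come from a lower level in input of the clones, and alone does not show more engagement by ribosomes. Ribosomal protein mRNAs had the highest values of the 24 lists: all 78 were positive, with a median log2 change of 1.01. In parental cells they were lower on polysomes than in input (median −0.74), in KO9 slightly higher (0.16) and in KO1 higher (0.38, or 0.03 without input KO1 replicate 2). RPS14 had 449 ± 3.15 RPKM in input and 278 ± 28.6 on polysomes of parental cells, against 290 ± 20.4 and 311 ± 0.117 in KO9 (n = 2 each). No single mRNA passed the test: RPS28 had 1.31 (SE 0.23, adjusted p = 0.483), RPS27 1.31, RPS14 1.21 and RPS19 1.18, each positive in both clones. Adjusted over the list alone, 60 of 78 were higher and none lower. The list's camera test gave adjusted p = 5.11e-67, and adjusted p = 0.147 with an estimated correlation, or up to 0.568 with 1 library also left out (input KO1 replicate 2); the lowest of any alternative was 1.02e-91. Fry, which asks only whether the list moved one way, gave 0.0696. The median stayed between 0.89 (without input KO1 replicate 2) and 1.24 (without replicate 1) with any 1 library left out, and was 0.71 without scaling and 0.43 with quantile normalization. The clones had medians of 1.15 (KO1; 0.81 without input KO1 replicate 2) and 0.92 (KO9).

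**Figure D3:**
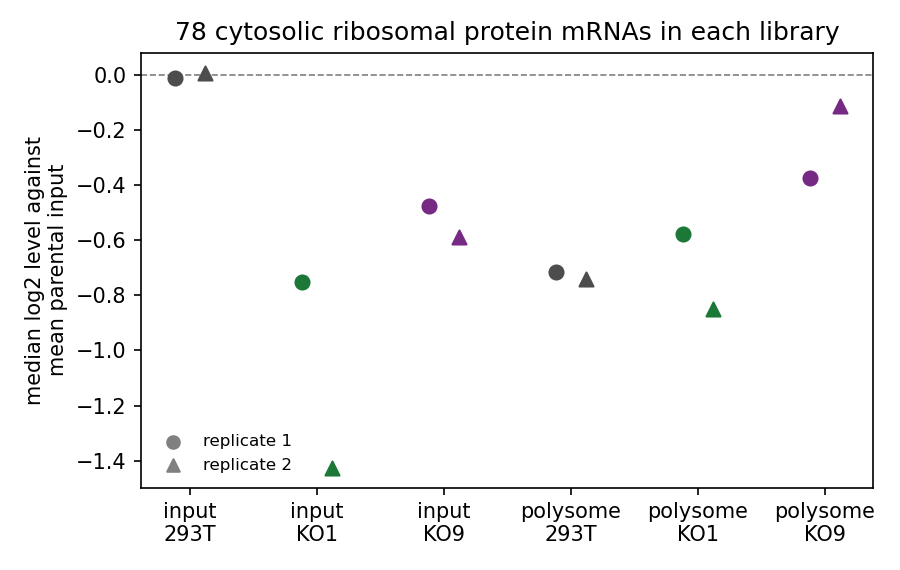
Median log2 level of 78 cytosolic ribosomal protein mRNAs in each of the 12 libraries against the mean of the parental input libraries (vertical axis); circles are replicate 1 and triangles replicate 2. Parental polysomes lay at −0.72 and −0.74, input KO1 at −0.75 and −1.43, input KO9 at −0.47 and −0.59, KO1 polysomes at −0.58 and −0.85, and KO9 polysomes at −0.37 and −0.11.

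Other lists with higher polysome over input were the respiratory chain (67 of 72 positive, median 0.39), other TOP mRNAs (17 of 18, 0.48; TPT1 1.01, RACK1 0.83), mitochondrial mRNAs (12 of 13, 0.54), mitochondrial ribosomal proteins (56 of 66, 0.16), proteasome (25 of 29, 0.22), noncoding hosts of small nucleolar RNAs (10 of 12, 0.22) and histones (5 of 7, 0.14). The small nucleolar RNA hosts had 0.48 in KO9 (10 of 12 positive) and −0.05 in KO1 (5 of 12), but 0.29 in KO1 (also 10 of 12) without input KO1 replicate 2. For both clones together, without input KO1 replicate 1 and 2, other TOP mRNAs had 0.76 and 0.32 and small nucleolar RNA hosts 0.06 and 0.39, while the proteasome had 0.34 without replicate 1 and histones 0.24 without replicate 2. Mitochondrial mRNAs had 0.34 without polysome KO1 replicate 1, and mitochondrial ribosomal proteins 0.24 without parental input replicate 1. Mitochondrial mRNAs are translated inside mitochondria, so their higher values do not measure engagement by cytosolic ribosomes. Higher values of other lists, ribosomal proteins included, therefore do not show engagement by themselves. Both clones had 0.38 for the respiratory chain, with 0.22 in KO9 without polysome KO9 replicate 2. The adjusted camera p-values of the 7 lists were 1.48e-17, 7.55e-07, 1.17e-06, 7.55e-07, 0.00172, 0.00422 and 0.0385, with no member past the threshold over all genes or adjusted over the list alone. With an estimated correlation the same lists, in that order, had adjusted p = 0.342, 0.410, 0.499, 0.499, 0.623, 0.623 and 0.342; with 1 library also left out they reached 0.888, and the lowest of any alternative was 1.45e-20. Without scaling the median of all genes was −0.27 rather than −0.03, and the medians of mitochondrial ribosomal proteins (−0.10), proteasome (−0.06), small nucleolar RNA hosts (−0.06) and histones (−0.03) turned negative; that of mitochondrial mRNAs turned to −0.18 with quantile normalization. Histones were no longer called without parental input replicate 2, input KO1 replicate 1, parental polysome replicate 1 or polysome KO9 replicate 2 (adjusted p up to 0.396), and small nucleolar RNA hosts without input KO1 replicate 1 (0.293).

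**Figure D4:**
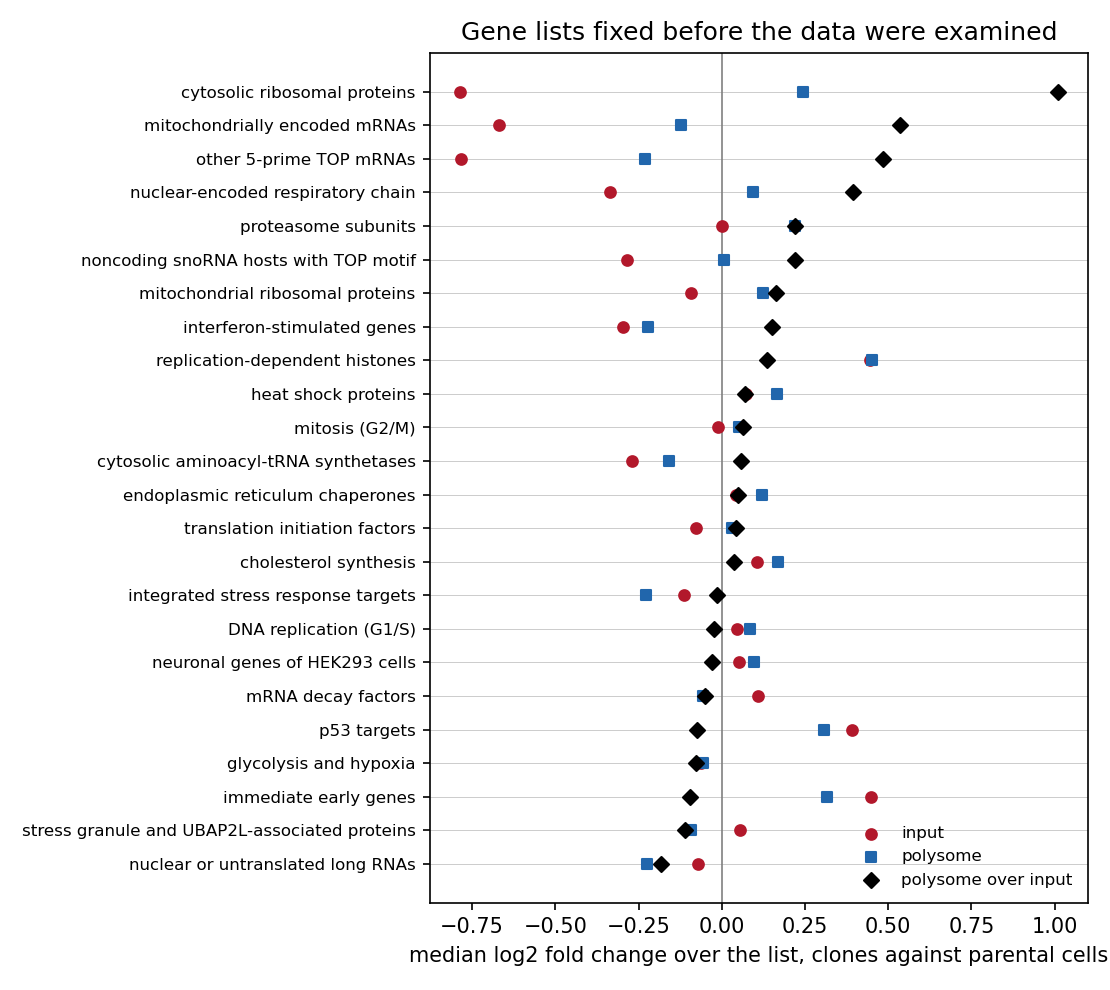
Median log2 fold change of each gene list, clones against parental cells (horizontal axis), in input, on polysomes and as polysome over input, 1 symbol each. Ribosomal proteins lay at −0.79, 0.24 and 1.01.

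In limma's test no gene passed for polysome over input with all libraries, where 635 had an unadjusted p under 0.05, and limma voom also called 0. Without input KO1 replicate 2 there were 173 genes (157 higher, 16 lower), with voom 479. Among the 173 were 44 ribosomal protein mRNAs, RPS28 (1.26), RPS27 (1.22) and RPS14 (1.06) among them, ATP5ME of the ATP synthase (0.94), TPT1 (0.83), RACK1 (0.76) and the respiratory chain subunit NDUFA3 (0.61), and, lower, PDZD8 (−0.61) and TARBP1 (−0.53). For RPS28 the adjusted p ranged from 0.000524 to 0.99999 over the alternatives. Among the lower values with all libraries were those of KPNA6 (−0.69), ZNF121 (−0.69), RNF168 (−0.53) and TARBP1 (−0.48), with adjusted p of at least 0.570. Without input KO1 replicate 1, 1784 genes passed, and without polysome KO9 replicate 2, 1. The 1784 held 65 ribosomal proteins, 31 respiratory chain subunits, 12 other TOP mRNAs, 10 mitochondrial ribosomal proteins and 10 proteasome subunits as higher, and 8 and 2 of the last 2 lists as lower. The 173 held 2 respiratory chain subunits and 2 other TOP mRNAs.

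Each clone was also compared with parental cells alone. In input 2147 genes passed in KO1 (1014 higher, 1133 lower) and 538 in KO9 (289 higher, 249 lower). The KO1 count was 224 and 143 without parental input replicate 1 and 2, 7247 and 3466 without input KO1 replicate 1 and 2, 1240 and 1233 without input KO9 and 1420 and 1417 without parental polysome replicate 1 and 2. The KO9 count was 63 and 31 without parental input, 3622 and 3623 without input KO1, 28 and 31 without input KO9, 262 and 260 without parental polysome, 301 and 302 without polysome KO1, and 342 and 341 without polysome KO9 replicate 1 and 2. On polysomes 799 genes passed in KO1 (333 higher, 466 lower) and 476 in KO9 (187 higher, 289 lower). The KO1 count there was 444 and 446 without parental input, 3713 and 3687 without input KO1, 412 without either input KO9 library, 98 and 113 without parental polysome, and 258 and 120 without polysome KO1 replicate 1 and 2. The KO9 count was 214 and 215 without parental input, 3821 and 3836 without input KO1, 164 and 172 without input KO9, 28 and 45 without parental polysome, 257 and 258 without polysome KO1, and 68 and 55 without polysome KO9 replicate 1 and 2. Without scaling the higher share of called genes was 85.2% rather than 47.2% in KO1 input, 87.9% rather than 53.7% in KO9 input and 20.4% rather than 39.3% on KO9 polysomes. For polysome over input no gene passed in KO1 (534 with an unadjusted p under 0.05; 4715 without input KO1 replicate 1; 0 by voom) or in KO9 (537 with an unadjusted p under 0.05; 121 and 118 without input KO1 replicate 1 and 2, and 1 without polysome KO9 replicate 2; 0 by voom).

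Genes called in both clones mostly moved the same way. No other knockout or mock-treated line was among the 12 libraries, so what goes with the lower UBAP2L mRNA cannot be separated from what the derivation of the clones brought. In input 126 were higher and 138 lower in both, where independent calls would give 25.2 and 24.3, and 21 were opposite. They were, without input KO1 replicate 2, 810 and 879, against 275 and 265, with 103 opposite, and without replicate 1 they were 951 and 928, against 593 and 537, with 571 opposite. With all libraries the excess over independent calls was 4.998 and 5.69 times. Its highest possible value falls as more genes are called, so it cannot be compared between these fits. Over all genes, Pearson r of the clones' input changes was 0.53 with all libraries, with the same sign in 67.9% of genes. Without input KO1 replicate 2 these were 0.60 and 72.8%, and without replicate 1 r was 0.37. The input counts were 8 and 13, and 1 and 8, without parental input replicate 1 and 2, 5 and 9, and 3 and 15, without input KO9 replicate 1 and 2, 54 and 67, and 54 and 66, without parental polysome replicate 1 and 2, 69 and 81 without either polysome KO1 library, and 75 and 88, and 74 and 88, without polysome KO9 replicate 1 and 2. On polysomes 56 were higher and 95 lower in both, against 5.36 and 11.6 (10.5 and 8.20 times), and 16 were opposite. They were, without input KO1 replicate 2, 829 and 866, against 298 and 311 (2.79 times each), with 147 opposite, and without replicate 1 they were 828 and 863 with 148 opposite. The polysome counts were 26 and 43, and 27 and 43, without parental input replicate 1 and 2, 21 and 37 without either input KO9 library, 4 and 5, and 4 and 11, without parental polysome, 18 and 30, and 15 and 20, without polysome KO1, and 14 and 21, and 10 and 19, without polysome KO9 replicate 1 and 2. Part of the excess may come from the shared parental libraries. Across genes, which are not independent replicates, the fold changes of the clones correlated with Pearson r 0.53 in input and 0.50 on polysomes. Both were taken against the same 2 parental libraries, which alone gave r 0.18 and 0.39 in simulations with unchanged clones. The covariances were 0.0840 and 0.0584, above the highest simulated values of 0.00663 and 0.00786, and no simulated pair shared a called gene. With each clone taken against a different parental library, the covariances were 0.0740 and 0.0826 in input (r 0.43 and 0.52), for KO1 against replicate 1 and against replicate 2, and 0.0557 and 0.0461 on polysomes (r 0.46 and 0.35). Here each clone had 1 parental library per fraction.

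The change in input and the change on polysomes, which use different libraries, were compared across genes for the clones together. Pearson r was 0.67, Spearman rho 0.67 and the slope by total least squares 0.76, and 74.8% of genes had the same sign. Gene length here is the merged exon length of a gene, not the length of an mRNA. The change of polysome over input was higher in genes of shorter length. Spearman with gene length was −0.52 in KO9 and −0.10 in KO1 (−0.51 without input KO1 replicate 2). For both clones together it was −0.35, ranging from −0.54 without input KO1 replicate 2 to −0.11 without replicate 1. The relation in KO9 was the same among protein-coding genes outside the ribosomal proteins (−0.52). Among these genes it was −0.01 in KO1 (−0.51 without input KO1 replicate 2) and −0.30 for both clones together. With GC content it was 0.28 in KO9 and −0.16 in KO1 (0.40 without input KO1 replicate 2). These 4 relations form 1 family, and no p-value is given, since genes are not independent.

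The lists here gave no call in the comparisons named with all libraries. For polysome against input the cytosolic ribosomal proteins had 5 higher and 15 lower of 78 (3 and 9 adjusted over the list alone) and a median of −0.05 (adjusted p = 0.508), which turned to 0.07 without scaling and to 0.12 with quantile normalization. This list was called lower without input KO1 replicate 2 (8 higher, 35 lower, median −0.15, adjusted p = 0.0436, or 0.971 with an estimated correlation), and without replicate 1 the counts were 22 and 19. Stress granule and UBAP2L-associated proteins had medians of 0.05 in input (0 higher, 1 lower of 34), −0.09 on polysomes (0 and 1) and −0.11 for polysome over input (adjusted p = 0.149), and 4 higher and 14 lower for polysome against input (0.0662). mRNA decay factors had 4 higher and 1 lower of 38 in input, 0 and 1 on polysomes and a median of −0.05 for polysome over input (0.0815). That median was 0.01 in KO1 with 20 of 38 positive, or −0.14 without input KO1 replicate 2, and −0.15 in KO9. Translation initiation factors had 1 higher of 33 in input and 1 on polysomes, endoplasmic reticulum chaperones 3 and 2 higher of 27, and genes of DNA replication 2 and 0 higher of 25, with none lower. Neuronal genes had 2 higher and 1 lower of 10 in either fraction, glycolysis and hypoxia 3 lower of 26 in either, cholesterol synthesis 1 higher of 22 in input, small nucleolar RNA hosts 3 lower of 12 in input, mitochondrial ribosomal proteins 1 lower of 66 in input and 1 higher on polysomes, and genes of mitosis none of 28. Of the long RNAs 1 was higher and 1 lower of 10 on polysomes. Adjusted over the list alone, the input counts (higher and lower) were 0 and 0 for stress granule proteins, 4 and 1 for decay factors, 0 and 0 for initiation factors, 4 and 0 for chaperones, 2 and 0 for DNA replication, 2 and 1 for neuronal genes, 0 and 3 for glycolysis, 1 and 0 for cholesterol synthesis, 1 and 4 for small nucleolar RNA hosts, and 0 and 0 for mitochondrial ribosomal proteins, mitosis and long RNAs. Lists came to be called without single libraries. In input, without input KO1 replicate 2, small nucleolar RNA hosts (adjusted p = 0.00918; 1 higher, 8 lower) and mitochondrial ribosomal proteins (0.0427; 1 and 10) were called lower, and heat shock genes (0.00946; 11 and 1), cholesterol synthesis (0.0359; 8 and 2), DNA replication (0.0359; 8 and 2) and stress granule proteins (0.0359; 13 and 3) higher, with adjusted p from 0.413 to 0.682 with an estimated correlation. On polysomes the same fit called immediate early genes (0.0432; 6 and 1) and mitochondrial ribosomal proteins (0.0432; 16 and 4) higher and other TOP mRNAs (0.0211; 1 and 8) lower, with 0.694, 0.805 and 0.694. For polysome against input synthetases (0.00259; 1 and 15) and stress granule proteins (0.00259; 5 and 20) were called lower, with 0.667 and 0.962. For polysome over input stress granule proteins (3.56e-06; 1 of 34 positive, median −0.19) and decay factors (0.000909; median −0.16) were called lower, with 0.685 and 0.573. The stress granule median for polysome over input was −0.01 in KO1 (−0.29 with 0 of 34 positive without input KO1 replicate 2). In KO9, whose value does not use that library, it was −0.21 with 2 of 34 positive. For KO9 against KO1 the median of this list was −0.55 and 0.06 without input KO1 replicate 1 and 2. The KO1 value thus rested on single libraries. Without parental input replicate 1 mitochondrial ribosomal proteins were called lower in input (0.00527), and decay factors (0.0329) and p53 targets (0.0117) lower for polysome over input, with 0.622, 0.631 and 0.469 with an estimated correlation. Without parental input replicate 2 small nucleolar RNA hosts were called lower (0.0363) and heat shock genes higher (0.0479) in input, with 0.579 each, and without input KO9 replicate 1 mitochondrial ribosomal proteins lower (0.0474), with 0.656. Without input KO1 replicate 1 the same 3 lists as without replicate 2 were called on polysomes in the same directions, with 0.703 to 0.802, and mitosis (0.000414), heat shock genes (0.0468) and synthetases (0.00551) higher for polysome over input, with 0.334, 0.765 and 0.689. Leaving out polysome KO1 replicate 2 or polysome KO9 replicate 1 called stress granule proteins lower for polysome against input (0.0355 and 0.0444, with 0.962 and 0.965) and over input (0.0220 and 0.0402, with 0.689 and 0.744). Synthetases were called lower for polysome against input without polysome KO1 replicate 2 (0.0417, with 0.695). For polysome over input decay factors were called lower without polysome KO9 replicate 1 (0.0454, with 0.744) and p53 targets without parental polysome replicate 2 (0.00346, with 0.428). On polysomes mitochondrial ribosomal proteins were called higher without parental polysome replicate 2 (0.0216), polysome KO1 replicate 2 (0.0465) or polysome KO9 replicate 1 (0.0138), with 0.647, 0.616 and 0.559. Immediate early genes (without polysome KO1 replicate 1), the respiratory chain (without polysome KO9 replicate 1) and mitochondrial mRNAs (without polysome KO1 replicate 2) were called higher there (0.0375, 0.0334 and 0.0465), and other TOP mRNAs lower without polysome KO9 replicate 2 (0.0298), with 0.583, 0.571, 0.616 and 0.601. In the 13 fits of each of these comparisons no list was called with an estimated correlation.

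The counts of the lists without a call moved as well. They were, without input KO1 replicate 2, higher and lower in input, 12 and 4 decay factors, 7 and 9 initiation factors, 8 and 3 chaperones, 2 and 5 genes of glycolysis, 6 and 1 of mitosis and 8 and 0 proteasome subunits. Without replicate 1, which keeps the divergent library, the balance differed: 10 and 10 decay factors, 6 and 12 initiation factors, 11 and 4 chaperones, 4 and 7 genes of glycolysis, 3 and 13 of mitosis, 7 and 12 proteasome subunits, 5 and 9 stress granule proteins, 6 and 5 heat shock genes, 5 and 2 genes of cholesterol synthesis, 7 and 3 of DNA replication, 17 and 25 mitochondrial ribosomal proteins, 1 and 4 small nucleolar RNA hosts, 3 and 3 neuronal genes and 2 and 2 long RNAs. On polysomes, without either replicate, they were 3 and 6 stress granule proteins, 4 and 7 decay factors, 4 and 5 initiation factors, 9 and 5 chaperones, 7 and 2 genes of DNA replication, 4 and 7 of glycolysis (3 and 7 without replicate 1), 7 and 5 of mitosis, 8 and 7 respiratory chain subunits (7 and 7), 16 and 4 mitochondrial ribosomal proteins (15 and 4) and 2 and 3 long RNAs. Without either parental input library none of these passed in input but neuronal genes (1 and 2 higher, without replicate 1 and 2), and without either parental polysome library none of those listed for polysomes passed there. Without either input KO9 library none of those in input passed but 1 heat shock gene, 1 gene of glycolysis (both without replicate 2) and 2 neuronal genes. Without either parental polysome library the higher decay factors in input numbered 1 and 2, and there was 1 chaperone, 1 proteasome subunit, 1 gene of DNA replication and no small nucleolar RNA host, initiation factor or gene of cholesterol synthesis. For polysome against input the lower stress granule proteins numbered 9 without parental input replicate 1, either input KO9 library, parental polysome replicate 1 or polysome KO1 replicate 1. The lower ribosomal proteins there numbered 9 without either input KO9 library, parental polysome replicate 2, polysome KO1 replicate 2 or polysome KO9 replicate 1.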

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

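The list tests between the clones were chosen after the data were seen, and the test on KO9 alone was chosen after the ribosomal protein result was seen.

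The clones differed from each other in input, by a test of KO9 against KO1. In limma's test 734 genes passed, 420 higher and 314 lower in KO9. FZD10 was lower in KO9 by −4.96 (log2, SE 0.12, adjusted p = 8.79e-09), and LYPD1, which modulates acetylcholine receptors, by −3.45 (adjusted p = 2.04e-05), with 12.9 ± 5.85 RPKM in KO1 and 0.167 ± 0.00573 in KO9 around 1.98 ± 0.00383 in parental cells. The secreted serpin SERPINF1 differed by −2.97 (adjusted p = 0.00777) and ZCCHC12 by −2.74 (adjusted p = 0.000279). In the other direction the lysosomal protease CTSZ differed by 3.24 (SE 0.13, adjusted p = 4.65e-07), with 7.46 ± 0.0235 RPKM in parental cells, 0.134 ± 0.0444 in KO1 and 9.49 ± 0.192 in KO9. ALDH1A2, an enzyme of retinoic acid synthesis, differed by 2.03 (adjusted p = 0.000132), LGALS3BP by 1.45 (adjusted p = 0.000107) and ECI2 by 1.42 (adjusted p = 0.0476). For SERPINF1 and ECI2 the difference was −1.89 and 0.66 without input KO1 replicate 2. The count was 367 and 366 without parental input replicate 1 and 2, 7045 and 1622 without input KO1, 83 and 83 without input KO9, and 405 and 406 without parental polysome replicate 1 and 2. Of the 734 genes 686 were among the 1622. Without scaling 38.6% of called genes were higher in KO9 rather than 57.2%. For polysome over input limma's test called 0 genes between the clones (175 with an unadjusted p under 0.05, 0 by voom, 5309 without input KO1 replicate 1, 1 without polysome KO9 replicate 2).

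Between the clones in input, the camera test had integrated stress response targets lower in KO9 (median −0.63, adjusted p = 5.24e-09, and 0.247 with an estimated correlation), with −0.55 (9.35e-12) without input KO1 replicate 2. Against parental cells these targets had a median of −0.53 in KO9 and of 0.15 in KO1, which was 0.30 and 0.02 without input KO1 replicate 1 and 2 and 0.31 and 0.08 without parental input replicate 1 and 2. Ribosomal proteins were higher in KO9 than in KO1 (0.57, adjusted p = 6.34e-08, and 0.974 with an estimated correlation), with 0.24 (0.000506) without input KO1 replicate 2. In input the test also called immediate early genes (−0.37, 0.00458) and cholesterol synthesis (−0.12, 0.0395) lower and mitochondrial mRNAs (0.54, 0.00663) and other TOP mRNAs (0.37, 0.0173) higher in KO9, with 0.974, 0.921, 0.974 and 0.974 with an estimated correlation. Of these, immediate early genes (median −0.16) and other TOP mRNAs (0.12) were lost without input KO1 replicate 2. Mitochondrial mRNAs, with a larger median of 0.73, and cholesterol synthesis, with −0.0012, were lost without replicate 1. Cholesterol synthesis was also lost without input KO9 replicate 2 (−0.10), and had −0.28 without input KO1 replicate 2. For polysome over input small nucleolar RNA hosts were higher in KO9 than in KO1 (0.52, adjusted p = 1.05e-05, and 0.969 with an estimated correlation), with 0.23 (1.23e-05) without input KO1 replicate 2. Leaving out single libraries added 7 calls in input and 27 for polysome over input, some of them in opposite directions: without input KO1 replicate 1 and 2 stress granule proteins were higher (0.44) and lower (−0.25) in KO9 in input. None of these calls held with an estimated correlation (0.404 at the lowest). No technical explanation was tested for the differences between the clones.

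Ribosomal protein mRNAs were higher for polysome over input in both clones (median 1.01). Correction for GC content and gene length left 1.01 (SE 0.042). Without input KO1 replicate 2 the same correction took the median from 0.89 to 0.78. Those biases may thus hold part of the change, and these values argue against them as the whole of it. KO9, which does not use input KO1 replicate 2, had 0.92 (SE 0.039), so that library alone is not the source. With each of the 4 parental libraries left out in turn the lowest median was 0.98 (SE 0.046), which argues against 1 aberrant parental library. The SEs of these medians were taken over the genes of the list, which are not independent. They do not measure the spread between libraries. Both parental inputs, which were the deepest libraries, being shifted as a pair stays open, as does reads shared with ribosomal protein pseudogenes. A biological change, by the lower UBAP2L or by the derivation of the clones, is an untested hypothesis.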

How the results depend on the processing

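Limma voom, the fit on protein-coding genes and the combinations with the library left out were chosen after the data were seen. Of 4972 alternative values for 194 named-gene results, 4354 kept direction and side of the threshold, 192 came to pass it, 420 no longer did and 6 reversed. The filter on low values removed no gene, so leaving it off tests nothing. The counts over the libraries left out in turn, lowest to highest, were 4697 to 8305 for polysome against input, 29 to 6075, 35 to 3892 and 0 to 1784 for the clones together in input, on polysomes and for polysome over input, 143 to 7247, 98 to 3713 and 0 to 4715 for KO1, 28 to 3623, 28 to 3836 and 0 to 121 for KO9, and 83 to 7045 and 0 to 5309 for KO9 against KO1 in input and polysome over input. In the order clones together, KO1, KO9 and KO9 against KO1, the input counts were 2848, 3853 and 977 with the deposited RPKM (first 3), and 7, 2, 5407 and 3 with the libraries of the comparison alone, where the spread comes from those libraries and so holds or lacks input KO1 replicate 2. Array weights gave 17, 5769 and 49 for KO1, KO9 and KO9 against KO1 in input. On polysomes the clones together, KO1 and KO9 had 3521, 3220 and 3039 with array weights and 2889, 3040 and 2919 with their own libraries. For KO9 polysome over input these gave 325 and 210. A minimum RPKM of 5, which tests fewer genes, left 376, 431 and 264 on polysomes, 250 for KO9 input and 372 for KO9 against KO1. The replicate number as a block gave 340 for KO9 input, and the correlations of the replicates of input with those of polysomes in the same line (−0.00, 0.04 and −0.11) gave no pairing. Voom without input KO1 replicate 2 gave 4929, 4203, 4322 and 2049 in input, 4012, 3956 and 3680 on polysomes and 479, 27 and 368 for polysome over input. Length and GC correction without that library left 54 for polysome over input, and parental cells alone, with fewer samples, 2204 for polysome against input. UBAP2L ranged over left-out libraries from −1.11 to −1.04 in input, −1.04 to −0.85 on polysomes and 0.03 to 0.23 for polysome over input, was −1.07 (adjusted p = 0.0553) with the input libraries alone, and reversed to −0.15 for polysome over input with the deposited RPKM. Called lists ranged from 4 to 9, 6 to 14, 5 to 11 and 7 to 10 over left-out libraries in the 4 main comparisons. With an estimated correlation they were 0, 0, 0 and 0, and fry gave 5 on polysomes and 0 for polysome over input. The clones' correlation ranged from 0.37 to 0.60 in input and 0.43 to 0.53 on polysomes, that of input with polysome change from 0.59 to 0.69, that with length from −0.54 to −0.11, and that with GC content from −0.20 to 0.36, reversed without input KO1 replicate 1 (−0.20), parental polysome replicate 2 (−0.12) and polysome KO1 replicate 2 (−0.03). Quantile normalization reversed MT-CO1 in input (0.076) and MT-CO2 (−0.30) and MT-ND4 (−0.28) for polysome over input. There H2BC12 reversed with length and GC correction without input KO1 replicate 2 (−0.11), H2BC21 with the deposited RPKM (−0.027) and CCNT1 without input KO1 replicate 1 (0.0015, from −0.56 to 0.0015 over left-out libraries). Ribosomal proteins for polysome against input reversed to 0.068 with the deposited RPKM and 0.049 without input KO1 replicate 1 (−0.15 to 0.049 over left-out libraries). Where no reason is given, the cause was not tested. In the shallowest library, polysome KO9 replicate 1, the median gene had 246 reads.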

Other observations

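The tests in this part were chosen before their results were seen.

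Input KO1 replicate 2 differed from replicate 1 by an SD of 0.650 across genes, against at most 0.220 in the other 5 pairs. After correction of each library for GC content and gene length 0.549 was left. Counting noise at the recovered reads gives 0.0716, so fewer reads do not explain it. Mixing the polysome KO1 libraries into replicate 1 lowered the SD at best to 0.570, at a share of 64%. Both input KO1 libraries had the KO1 levels of FZD10 and CTSZ. FZD10 had 66.8 ± 5.31 RPKM, against 0.397 in parental input and 1.06 in input KO9. CTSZ had 0.134 ± 0.0444, against 7.46 and 9.49. SERPINF1 differed widely between the 2 libraries (40.8 ± 37.8). FZD10 and CTSZ, picked after the data were seen, argue against a sample wholly from parental cells or KO9. RNA quality, another culture state, a mixture and a sample of other origin were not tested and stay open.

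The clones changed together on polysomes, with a covariance of 0.0584 between their fold changes across genes. The shared parental libraries alone gave at most 0.00786 in 100 simulations with unchanged clones, so they do not account for it. A difference of both parental polysome libraries from all clone libraries for a reason other than UBAP2L stays open, and so does a change common to derived lines.

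For polysome against input, with the line as an additive term, 5926 genes passed, and the highest of the other splits of the 12 libraries gave 4070. Only 1 of the 100 splits, the real one, reached as many. A share of 1 in 100 is the lowest that 100 splits can give, so chance is unlikely but not excluded.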
